A study of Mus musculus with 64 samples.

How the data were processed

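The series covers 64 samples of colon from T cell transfer colitis in SCID and Rag2-deficient mice, of which 9 surface protein libraries of the sorted immune fraction (EpCAM- and CD45+) of SCID mice were used. The other 55 samples, RNA libraries included, were not analysed here. Per the labels' protocols, tissue of 3 animals was pooled, lamina propria cells were stained with tagged antibodies against 11 proteins, and about 16000 cells per sample were loaded on a droplet instrument. SCID tissue was collected every 7 days and anti-IL-12p40 was given from day 10, per the series' design text. The deposited values are whole-number counts of each antibody per barcode, not normalized. The submitters' processing notes name Cell Ranger 6.0.2, Seurat 4.1.1 and the genome build mm10, with no role for each. How barcodes were selected is not given in the sources used here. In 3 libraries the barcodes outnumbered the loaded cells. Library pairs shared 30 to 110 barcodes, and no library was a copy of another.

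Barcodes with fewer than 50 antibody counts and the top 1% of each library by total were left out, which kept 130442 of 131917 barcodes. No doublet caller was run, since the antibody counts alone give none its usual input, and doublets within the lower 99% remain. Each count was transformed to a centred log ratio, the natural log of the count plus 1 minus the cell's mean over the 11 antibodies. A cell was positive above the point where both components of a 2-component Gaussian mixture were equally probable, fitted once per antibody on 2000 cells from each library. Ashman's D, the distance between the components in units of their spread, was below 2 for CD127 (1.56) and Ly-6C (1.82), which were called not separable. Cells were placed in 9 exclusive phenotypes in a fixed order: CD3+CD4+, CD3+CD4-, CD11b+Ly-6G+, CD11b+Ly-6C+CD64-, CD11b+Ly-6C+CD64+, CD64+Ly-6C-, CD11c+CD64-, CD3-CD90.2+ without CD11b, CD11c and CD64, and all others. Cell type names are background only. The panel held no epithelial, stromal or B cell marker.

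Trends across the 8 untreated libraries were tested by Spearman's rank correlation with week, with a two-sided exact permutation p over all 40320 orderings and Benjamini-Hochberg adjustment within each of 3 families (11 antibodies, 9 phenotypes, 15 within-phenotype shares) at 0.05. A within-phenotype trend used libraries with at least 50 cells in the phenotype. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Treated against untreated is 1 library against 1, so no test was made. All antibodies and phenotypes are named. Within-phenotype shares are named where the adjusted p was below 0.05 or the treated library differed by the size rule, and otherwise given as a range. These choices, the gates and the main list of alternatives were made before the data were examined. Alternatives were another scaling, thinning to 164 counts per cell, with shallower cells left out, other thresholds, count filters, k-means clusters, leaving out each library, other trend statistics and threshold-free summaries. Shares among CD3- cells, also with each library left out, a CD4+CD90.2+ phenotype defined without CD3, and proteins within CD4- cells of the CD3-CD90.2+ phenotype were added after seeing the data.

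The steps were tested on simulated data for the 9 phenotypes. With 8000 cells per library drawn from the means and covariances of each phenotype, the rank correlation of true and recovered shares over libraries was 0.929 to 1.00 for 7 phenotypes and 0.667 for CD3+CD4- cells. The median error was 0.138 percentage points for CD11b+Ly-6G+ cells and 2.03 for CD3+CD4+ cells. When antibodies were drawn independently of each other, which removes the depth a cell's antibodies share, recovery was poorer: 0.417 for CD11b+Ly-6G+ and 0.400 for CD3+CD4- cells. With independent draws at 0.6 of the spread it was 0.904 to 1.00 for the 8 phenotypes. Each form drew on real cells gated by the same thresholds and pooled over libraries, which makes recovery easier. Cells in no phenotype, shifts of a protein between libraries and shared droplets were not simulated. In 100 simulated sets of 9 trends with the real spread between libraries (SD 0.815 on the logit scale), 4.75% of trends with an odds change of 4 times were called, 32.0% at 16 times and 81.8% at 64 times. Unchanged phenotypes were called in 0.800% to 1.40% of cases. The exact test has a size of 4.58% at 0.05 without ties. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.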

Results

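Surface proteins were counted on single immune cells from the colon of SCID mice during T cell transfer colitis. SCID mice lack their own T and B lymphocytes, and transferred CD45RBhi T cells, a naive T cell fraction, cause colitis in such hosts. Antibodies carrying sequence tags were counted for 11 proteins. CD3, CD4 and CD90.2 mark T cells, with CD90.2 also on innate lymphoid cells. CD127 is the interleukin-7 receptor and KLRG1 a lectin-like receptor of lymphocytes. CD103 is an integrin of mucosal T and dendritic cells. CD11b, CD11c, CD64, Ly-6C and Ly-6G mark myeloid cells. There were 9 libraries, 1 from each of weeks 0 to 7 without treatment and 1 from week 7 of mice given anti-IL-12p40, an antibody against the subunit shared by IL-12 and IL-23. Each library pooled tissue from 3 animals. The libraries held 11534 to 21229 barcodes and 12914066 to 28723452 antibody counts. The median per cell was lowest at week 1 (576.5 counts) and highest in the treated library (1566 counts). It had a rank correlation of 0.643 with week across the 8 untreated libraries (exact permutation p = 0.0962; Pearson r = 0.637, exact p = 0.0909). Cells are not replicates, so intervals given here are exact binomial 95% intervals for counting error only. The p-values measure how unusual the relation with week is among all orderings of the pools. With 1 pool per week, the spread between pools of the same week is unknown.

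The first comparison asked how the immune infiltrate changed with time after transfer. CD4+ cells rose from 11.7% of cells at week 0 to 92.1% at week 7, and CD3+ cells rose from 0.604% to 88.1%. Cells carrying both proteins, the phenotype of helper T cells, were 1 of 16735 cells at week 0, 4.77% at week 1, 39.2% at week 2 and 87.6% (87.0 to 88.2) at week 7. CD11b+Ly-6G+ cells, the phenotype of neutrophils, rose from 0.747% (0.622 to 0.889) to 5.42% (5.02 to 5.84), with the highest share, 6.11%, at week 4. CD64+Ly-6C- cells, the phenotype of tissue macrophages, fell from 19.7% to 0.529%, and CD11c+CD64- cells, which include dendritic cells, fell from 28.5% to 1.60%. At week 0 the CD4- cells of the CD64+Ly-6C- phenotype had a median of 676 CD90.2 counts, against 925 in CD3-CD90.2+ cells. In the untreated libraries of weeks 1 to 7 that median was 26 to 104. Doublets were not removed, so the week 0 share may include droplets shared with CD90.2+ cells, which was not tested. At week 4 the CD64+Ly-6C- share was 17.2%, above those of weeks 3 and 5.

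Of the 11 antibodies, 2 passed the exact permutation test of rank correlation with week after Benjamini-Hochberg adjustment, and 5 had an unadjusted p under 0.05. The rank correlation was 0.952 for CD4 (exact p = 0.00114, adjusted p = 0.0125; Pearson r = 0.948, exact p = 0.000496). It was 0.881 for CD3 (exact p = 0.00724, adjusted p = 0.0398; Pearson r = 0.906, exact p = 0.00179). Of the 9 phenotypes, 4 passed and 5 had an unadjusted p under 0.05. The rank correlation was 0.881 for CD3+CD4+ cells (exact p = 0.00724, adjusted p = 0.0461; Pearson r = 0.912, exact p = 0.00169). It was 0.810 for CD11b+Ly-6G+ cells (exact p = 0.0218, adjusted p = 0.0490; Pearson r = 0.844, exact p = 0.0104). CD64+Ly-6C- and CD11c+CD64- cells both had -0.833 (exact p = 0.0154, adjusted p = 0.0461), with Pearson r of -0.822 (exact p = 0.0152) and -0.841 (exact p = 0.00313). Without weeks 0 and 7 the rank correlation was 0.886 for CD4 (exact p = 0.0333). For CD3, CD3+CD4+ and CD11b+Ly-6G+ cells it was 0.714 (exact p = 0.136), with Pearson r of 0.775, 0.792 and 0.712. For both falling phenotypes it was -0.600 (exact p = 0.242), with Pearson r of -0.558 for CD64+Ly-6C- and -0.688 for CD11c+CD64- cells. Those 5 relations kept their sign but did not pass in the 6 libraries between the end weeks.

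No antibody passed without week 0, 1 or 2 (lowest exact adjusted p = 0.0742), where the rank correlation was 0.929 for CD4 and 0.821 for CD3. No phenotype passed without week 0, 1, 2 or 7 (exact adjusted p = 0.132 to 0.154 and rank correlation 0.821 for CD3+CD4+ cells). No phenotype passed with cells thinned to 164 counts either, which left out shallower cells, from 0.167% of the library at week 3 to 9.97% at week 1 (lowest exact adjusted p = 0.0653). The rank correlations were then 0.810 for CD11b+Ly-6G+ and -0.833 for CD11c+CD64- cells, as without thinning, 0.833 for CD3+CD4+ and -0.738 for CD64+Ly-6C- cells. Without single other weeks, exact adjusted p was 0.0677 (week 5) and 0.125 (week 7) for CD3. It was 0.0536 to 0.0864 for CD11b+Ly-6G+ cells without week 3 or 6, CD64+Ly-6C- cells without week 3, 5 or 6 and CD11c+CD64- cells without week 4 or 6. With thresholds fitted in each library the rank correlation was -0.381 for CD64+Ly-6C- cells (exact adjusted p = 0.463), a phenotype that rests in part on Ly-6C, which was not separable. It was then -0.667 for CD11c+CD64- (exact adjusted p = 0.173), 0.738 for CD11b+Ly-6G+ (0.138) and 0.714 for CD3+ cells (0.238). CD3+ cells also missed with counts scaled to the library median (rank correlation 0.857, exact adjusted p = 0.0589) and when thinned (0.833, exact adjusted p = 0.0846). The CD3 trend missed as well when taken as a mean centred log ratio or as a percent of all antibody counts. With k-means clusters CD11b+Ly-6G+ (0.714, exact adjusted p = 0.0672) and CD64+Ly-6C- cells (-0.738, exact adjusted p = 0.0642) missed. CD4+CD90.2+ cells without CD11b, CD11c and CD64, a phenotype that does not use CD3 and was chosen after the data were seen, rose from 3.13% at week 0 to 86.1% at week 7 (rank correlation 0.976, exact adjusted p = 0.00357). Of these cells 0.191% were CD3+ at week 0, with a median of 2 CD3 counts, and 53.1% at week 1. The share was 78.5% to 97.9% at weeks 2 to 7, so the phenotype does not stand for T cells at week 0.

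**Figure D1:**
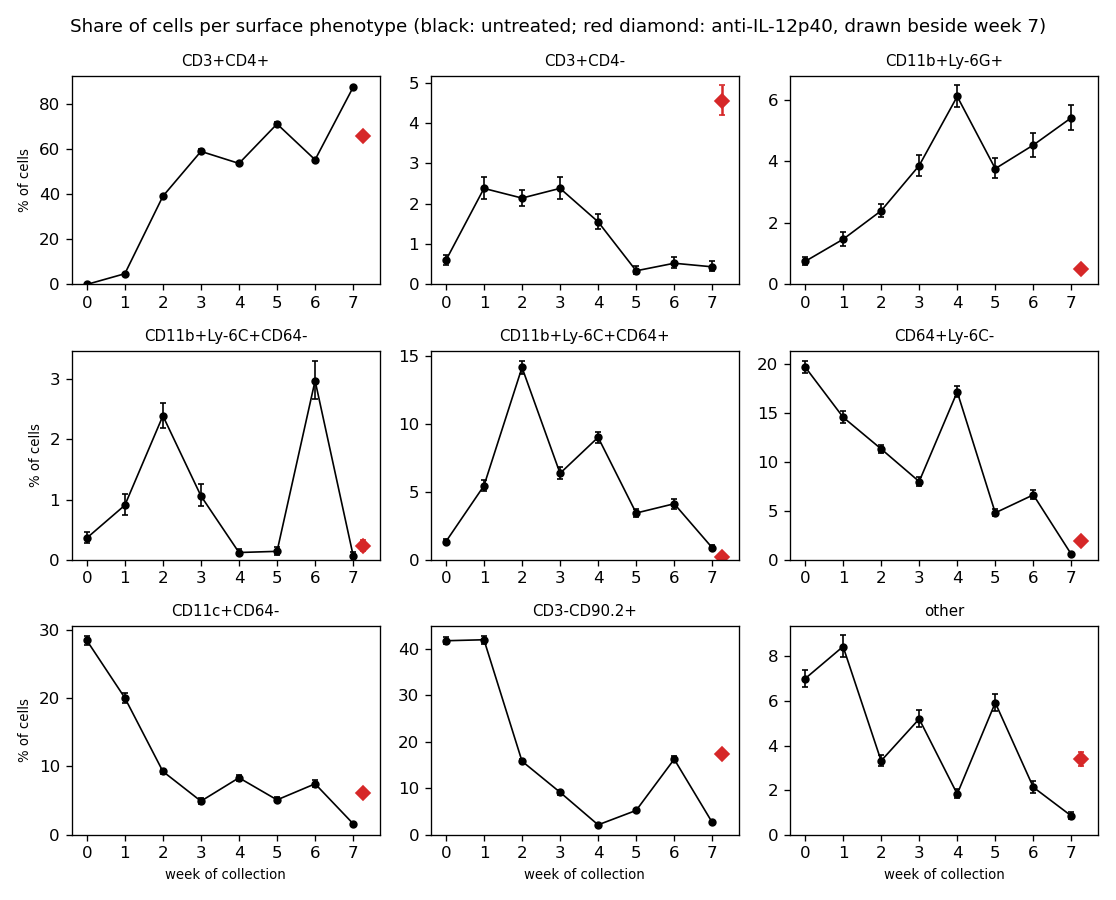
Share of cells (%) per surface phenotype against week of collection. Black points joined by lines are the 8 untreated libraries, the red diamond beside week 7 is the anti-IL-12p40 library, and bars are exact binomial 95% intervals. CD3+CD4+ cells go from under 5% at weeks 0 and 1 to 87.6% at week 7, and the treated library has 0.490% CD11b+Ly-6G+ cells against 5.42% without treatment.

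All shares are parts of one whole, and the decline of myeloid phenotypes was measured beside a growing T cell share. Among CD3- cells alone, CD11b+Ly-6G+ cells were 0.751% at week 0, 10.0% to 13.7% at weeks 3 to 6 and 45.4%, or 645 of 1422 cells, at week 7 (rank correlation 0.905, exact p = 0.00456, adjusted p = 0.0319). Without week 7 the rank correlation was 0.857 and did not pass (exact p = 0.0238, adjusted p = 0.167), as without week 0, 1, 2 or 3, each at the same values. CD64+Ly-6C- cells went from 19.9% to 4.43% and CD11c+CD64- cells from 28.7% to 13.4% of CD3- cells, and neither passed (exact adjusted p = 0.378 for both). This denominator, and leaving out libraries under it, were chosen after the data were seen. It can still hold cells resembling T cells with little CD3. At week 6, 1696 of the 5031 CD3- cells were CD4+ cells of the CD3-CD90.2+ phenotype, which lowers the other shares of that week.

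The remaining proteins did not pass the adjusted exact test of rank correlation, the test fixed for this comparison, although 3 of them had a Pearson correlation with adjusted p under 0.05. KLRG1+ cells were 26.7% to 32.8% of cells at weeks 0 to 3 and 7.39% to 11.8% at weeks 4 to 7 (rank correlation -0.810, exact p = 0.0218, adjusted p = 0.0798; Pearson r = -0.862, exact p = 0.0125, adjusted p = 0.0333). Without weeks 0 and 7 the rank correlation was -0.943 for KLRG1 (exact p = 0.0167). CD11c+ cells were 39.3% at week 0 and 2.96% at week 7, and Ly-6G+ cells 0.747% and 6.53% (exact adjusted p = 0.0905 for both). Their Pearson r was -0.831 and 0.820 (exact adjusted p = 0.0333 for both), and -0.606 and 0.642 without weeks 0 and 7. CD90.2+ cells ranged from 53.1% to 90.7%, CD103+ cells from 7.63% to 28.8%, CD11b+ cells from 8.94% to 38.1% and CD64+ cells from 1.53% to 31.9%. For CD127 and Ly-6C the positive and negative populations were not separable, and their shares of 28.7% to 67.8% and 2.49% to 30.2% depend on where the threshold falls. CD11b+Ly-6C+CD64+ cells, between monocytes and macrophages in phenotype, were highest at week 2 (14.1%), and CD11b+Ly-6C+CD64- cells, the phenotype of monocytes, at week 6 (2.98%). Both phenotypes rest on Ly-6C and so depend on its threshold, at a centred log ratio of 3.16. The background peak of Ly-6C lay at 2.65 at week 2, against 1.65 to 2.15 at the other untreated weeks, which may raise the week 2 share. CD3-CD90.2+ cells without myeloid markers, which include innate lymphoid cells, were 41.8% at week 0, 2.12% at week 4, 16.3% at week 6 and 2.62% at week 7 (rank correlation -0.643, exact adjusted p = 0.144; Pearson r = -0.788, exact adjusted p = 0.0354, and -0.625 without weeks 0 and 7). CD3+CD4- cells ranged from 0.338% to 2.38% and cells in no phenotype from 0.840% to 8.44%. With 8 libraries a miss does not show a flat course: in simulated series, a change in odds of 16 times between week 0 and week 7 was called in 32.0% of cases.

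Within phenotypes, the question was what share of the cells carried a given protein. CD4 was carried by 7.48% of CD3-CD90.2+ cells at week 0 and 68.3% at week 7, with 91.4% at week 6. This was the 1 of 15 within-phenotype shares that passed (rank correlation 0.976, exact p = 0.000397, adjusted p = 0.00595; Pearson r = 0.912, exact p = 0.00258; without weeks 0 and 7, 1.00 with exact p = 0.00278). The makeup of this phenotype changed with it: its CD4- cells went from 38.6% to 0.831% of the library, while its CD4+ cells were 3.13% at week 0, 0.994% at week 4, 14.9% at week 6 and 1.79% at week 7. Another 4 within-phenotype shares had an unadjusted p under 0.05. In the week 6 library these cells had a median of 16 CD3 and 202 CD4 counts, against 36 and 216 in CD3+CD4+ cells. With counts scaled to the library median in place of the centred log ratio the CD4 trend did not pass (rank correlation 0.857, exact adjusted p = 0.161). CD4 also passed on more CD11b+Ly-6G+ cells, which should lack it, late than early: 4.80% at week 0 and 38.0% at week 7. The other 14 rank correlations ranged from -0.929 to 0.786, with adjusted exact p from 0.0506 upward.

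The second comparison asked how neutralising IL-12p40 changed the infiltrate at week 7. The treated library had fewer CD11b+Ly-6G+ cells, 0.490% (0.375 to 0.630) against 5.42% (5.02 to 5.84) without treatment, a ratio of 0.0905. It had more CD3-CD90.2+ cells, 17.3% (16.6 to 18.0) against 2.62% (2.34 to 2.92), a ratio of 6.60. KLRG1+ cells were 26.7% against 11.8% of all cells, and within CD3-CD90.2+ cells KLRG1 was carried by 49.7% (47.6 to 51.9) against 15.7% (11.9 to 20.2). Those cells differed in composition, 13.5% being CD4+ with treatment and 68.3% without. Within their CD4- part alone, chosen after the data were seen, KLRG1 was carried by 53.8% (51.5 to 56.1) of 1861 against 28.3% (19.7 to 38.2) of 99 cells, a ratio of 1.90. CD3+CD4+ cells were 65.8% (64.9 to 66.6) against 87.6% (87.0 to 88.2), and CD3+ cells 70.3% against 88.1%, both inside the range of untreated weeks 5 to 7. Week 6 alone sets the lower end of that range, at 55.4% and 55.9%, and had a lower CD3 signal on its CD4+ cells. Both treated shares lay below those of week 5, 71.3% and 71.6%. CD4+CD90.2+ cells defined without CD3 were 65.6% in the treated library, 61.5% at week 5 and 86.1% at week 7. CD4+ cells were 69.7% against 92.1%, below the 75.1% to 92.1% of those weeks but with a ratio of 0.756. CD11b+Ly-6C+CD64+ cells, which rest on Ly-6C, not separable here, were 0.201% against 0.865%. CD11c+ (7.73% against 2.96%), CD64+ (2.93% against 1.53%), CD64+Ly-6C- (1.93% against 0.529%), CD11c+CD64- (6.15% against 1.60%) and CD11b+Ly-6C+CD64- cells (0.225% against 0.0672%) and cells in no phenotype (3.38% against 0.840%) were higher but within the range of untreated weeks 5 to 7. CD90.2+ cells were 91.8% against 90.7%, CD103+ cells 28.3% against 23.7%, and CD127+ cells, not separable, 64.5% against 64.4%. The CD90.2+ and CD103+ shares lay above the highest of those weeks (90.7% and 24.6%), with ratios of 1.01 and 1.20.

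This comparison is 1 library against 1, so there is no test and no replicate check. A difference was called large if the ratio was at least 1.5 either way, the intervals did not overlap and the treated share lay outside the untreated shares of weeks 5 to 7. That held for 8 of 20 antibodies and phenotypes, 3 higher and 5 lower in the treated library. Besides those above, they were CD11b+ cells (5.20% against 8.94%), Ly-6G+ cells (0.627% against 6.53%), Ly-6C+ cells (1.45% against 3.07%, with Ly-6C not separable) and CD3+CD4- cells (4.55% against 0.437%). Simulated CD3+CD4- shares were recovered with errors of up to 4.13 percentage points when drawn with covariances, as large as that difference. The largest error was 14.6 points when antibodies were drawn independently. The 52 untreated CD3+CD4- cells had a median of 393 counts in all and 9 for CD3, against 1106 and 27 in the 566 treated ones. The CD3+CD4- ratio of 10.4 ranged from 2.26 to 14.1 over the alternatives that gave it. The CD11b+ and Ly-6G+ differences overlap with that of CD11b+Ly-6G+ cells. In the untreated library 645 cells had that phenotype, of 778 Ly-6G+ and 1065 CD11b+ cells. CD3-CD11b+Ly-6G- cells were 408 of 12437 treated and 237 of 11907 untreated cells. CD11b+ cells without CD3 and Ly-6G thus did not have a lower share with treatment. The CD3-CD90.2+ share of 17.3% lay just above the 16.3% of untreated week 6, most of which was CD4+. Its CD4- part was 15.0% in the treated library and 0.831% to 1.88% at weeks 5 to 7. Calls of large were lost for CD3-CD90.2+ cells when thinned to 164 counts (2.70), which left out 3.57% of treated and 0.470% of untreated cells, or thresholds fitted in each library (4.82), for KLRG1+ cells with such thresholds (1.36), and for CD11b+ (0.716) and Ly-6C+ cells (0.724) with counts scaled to the library median. With thresholds fitted in each library the Ly-6G+ and Ly-6C+ ratios turned to 6.48 and 3.24, while that for CD11b+Ly-6G+ cells was 0.532.

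**Figure D2:**
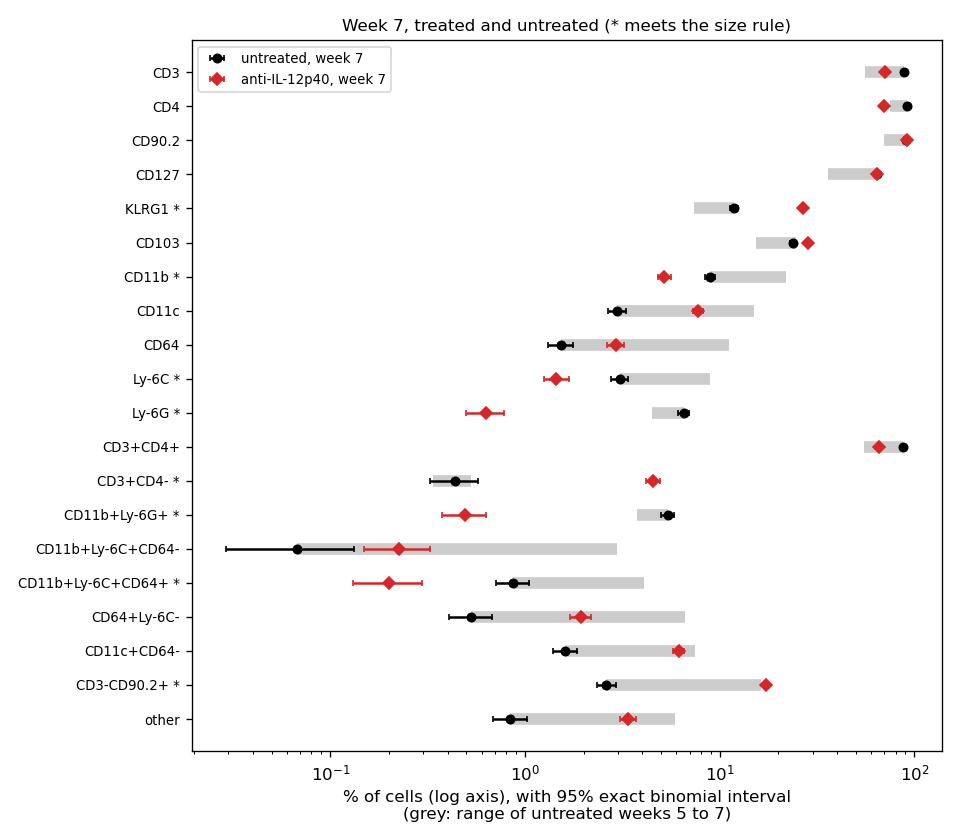
Share of cells (%, log axis) at week 7 per antibody and phenotype, treated (red diamonds) and untreated (black points), with exact binomial 95% intervals. Grey bars span untreated weeks 5 to 7, and asterisks mark the 8 differences called large, among them Ly-6G+ cells at 0.627% against 6.53%.

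Within phenotypes 7 of 15 shares differed by the same rule, 3 higher and 4 lower. KLRG1 was carried by 20.7% of CD3+CD4+ cells with treatment and 12.3% without, but the call was lost with thresholds fitted in each library (0.989), counts scaled to the library median (1.31) and k-means clusters (1.42). CD4 was carried by 13.5% against 68.3% of CD3-CD90.2+ cells. On CD11b+Ly-6G+ cells, which should lack CD4, it passed on 14.8% against 38.0%. CD103 was carried by 21.4% against 44.6% of CD3-CD90.2+ cells. For CD103 the call was lost with scaled counts (0.883), thinning (0.708), k-means clusters (1.26) and in the CD4- part (0.814). Of CD3-CD11b+Ly-6G- cells, which include monocytes and macrophages, 13.0% (9.88 to 16.6) against 46.8% (40.3 to 53.4) passed as Ly-6C+, a protein not separable here. CD64 was carried by 35.5% against 67.5% of them, a ratio of 0.526 that was 0.698 with thinning, 0.936 with thresholds fitted in each library and 1.00 with k-means clusters, each ending the call. CD103 was carried by 14.5% (11.2 to 18.3) against 2.95%, the latter being 7 of 237 cells. Untreated week 5 had 12.0% (10.4 to 13.8), an interval that overlaps the treated one. The ratio of 4.90 ranged from 2.65 to 14.4 over the alternatives. The other 8 ratios ranged from 0.872 to 1.34.

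**Figure D3:**
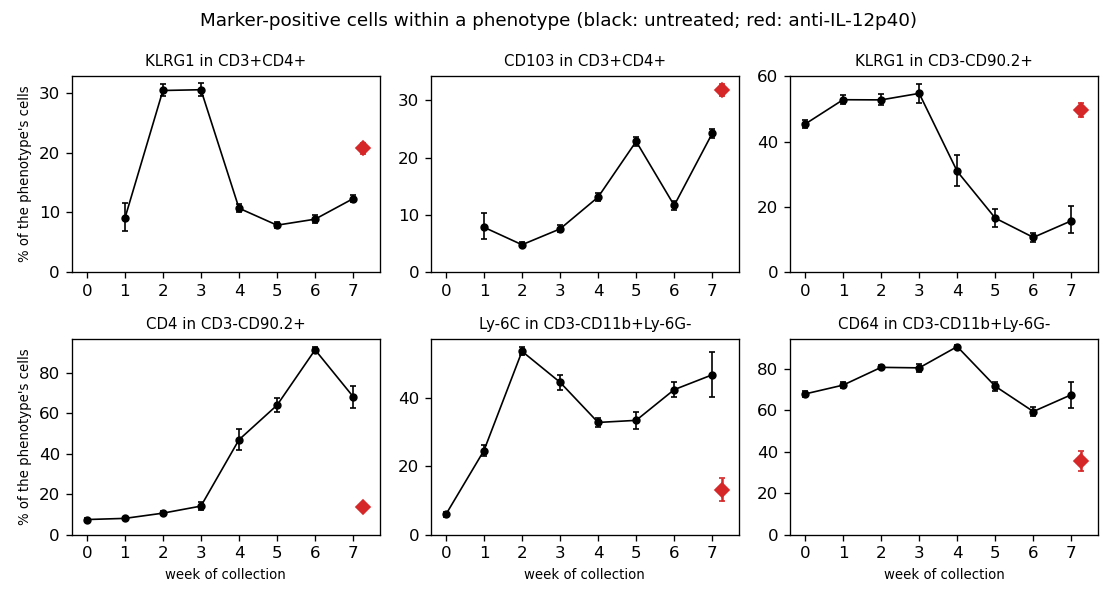
Marker-positive cells as a share (%) of the cells of a phenotype against week of collection, for 6 pairs of marker and phenotype. Black points joined by lines are untreated libraries with at least 50 cells in the phenotype, red diamonds the treated library, and bars exact binomial 95% intervals. KLRG1 within CD3-CD90.2+ cells is 15.7% in the untreated and 49.7% in the treated library at week 7.

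Background was read from cells that should lack a protein. Ly-6G passed on 0.142% to 1.62% of CD3+CD4+ cells over 8 libraries. It passed on 0.147% (0.0758 to 0.256) in the treated library, where CD11b+Ly-6G+ cells were 0.490% (0.375 to 0.630). At untreated week 7 it passed on 1.15% (0.955 to 1.37), where CD11b+Ly-6G+ cells were 5.42% (5.02 to 5.84). Median Ly-6G on CD3+CD4+ cells was 2 counts in the treated and 10 in the untreated week 7 library. On CD11b+Ly-6G+ cells CD4 passed on 4.80% (1.78 to 10.2) at week 0 and 8.50% to 12.4% at weeks 1 to 4. It passed on 36.7%, 21.3% and 38.0% at weeks 5, 6 and 7 and on 14.8% in the treated library. KLRG1 passed on 14.4% of these cells at week 0, 0.774% at week 6, 1.86% at week 7 and 6.56% in the treated library. The CD4 and KLRG1 backgrounds moved in the directions reported above for these proteins. Between the treated and untreated week 7 libraries the Ly-6G background did so too. Background may be part of those differences, which was not tested.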

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

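Counts of passing trends depended on the processing more than the directions of those trends did. Of 672 trend values recomputed, leaving aside a split of the weeks, 577 stayed on the same side of the threshold, 69 lost it and 26 gained it. None that passed turned direction. The 577 include trends that passed in neither case. With the split counted, CD3 passed again in 9 of 20 settings and CD4 in 16 of 20. It was 13 of 19 for CD3+CD4+, 12 of 27 for CD11b+Ly-6G+, 7 of 27 for CD64+Ly-6C- and 9 of 27 for CD11c+CD64- cells. CD4 within CD3-CD90.2+ cells passed in 15 of 17. Some trends that missed at first changed sign, such as Ly-6G (correlation -0.429 to 0.893). Antibodies passing went from 2 to 1 with counts scaled to the library median, 1 when thinned, 1 with thresholds per library, 5 with Pearson correlation of logit shares and 1 with the mean centred log ratio. Phenotypes passing went from 4 to 7 when scaled, 0 when thinned (4 unadjusted), 2 with thresholds per library and, for the 7 phenotypes outside CD3+ cells, from 3 to 1 among CD3- cells (0 to 1 with a library left out as well), alternatives added after seeing the data. Within-phenotype shares passing went from 1 to 0 when scaled, 4 with thresholds per library and 3 with Pearson correlation of logit shares. For weeks 0 to 3 against 4 to 7, 0 antibodies, 0 phenotypes and 0 within-phenotype shares passed, which says nothing about stability. With 4 libraries against 4 the smallest exact p is 0.0286, and at least 7 antibodies, 6 phenotypes or 9 within-phenotype shares would have to reach it to pass after adjustment. Unadjusted exact p was under 0.05 for 1, 0 and 3 of them. Leaving out 1 library gave 0 to 8 antibodies, 0 to 4 phenotypes and 1 to 2 within-phenotype shares. No antibody passed without week 0, 1 or 2, no phenotype without week 0, 1, 2 or 7, and 8 antibodies passed without week 4. Fewer libraries lower the power of the exact test. The causes of the other changes were not tested. No paired analysis was possible because each group held 1 library.

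Of the 8 large differences at week 7, those large in the same direction numbered 4 with thresholds per library, 6 when scaled, 7 when thinned, 7 with k-means clusters, which gave no ratio for CD3+CD4- cells, and 8 with Otsu's threshold, other count minimums or the top 1% kept. Among CD3- cells 3 of the 8 could be recomputed, and those 3 stayed large. They share a denominator, so a fall in CD11b+Ly-6G+ cells raises the CD3-CD90.2+ share there. Of 283 treated to untreated ratios recomputed, 189 stayed within the counting interval of the first value, 87 moved outside it and 7 turned direction. By the size rule 259 kept their side, 15 lost a call and 9 gained one. With counts scaled to the library median, the ratio for Ly-6C within CD3+CD4+ cells turned to 0.447 and for CD11c within CD3-CD11b+Ly-6G- cells to 1.81, and with Otsu's threshold the former to 0.587. With thresholds per library the ratio turned to 3.24 for Ly-6C, 6.48 for Ly-6G and 0.989 for KLRG1 within CD3+CD4+ cells. With k-means clusters that for CD103 within CD3-CD90.2+ cells turned to 1.26. The cause was not tested. The ratio ranged from 0.0364 to 0.532 for CD11b+Ly-6G+ cells, 2.66 to 28.7 for CD3-CD90.2+ cells and 1.90 to 3.76 for KLRG1 within them, the lowest in their CD4- part, also added after seeing the data.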

Other observations

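All tests in this part were chosen after the results were seen. The cells carrying KLRG1 and CD103 fell in other phenotypes at week 7 than at week 0, close to the makeup of the week 7 library as a whole. At week 0, 64.6% of KLRG1+ cells were CD3-CD90.2+, against 41.8% of all cells, and 62.6% of CD103+ cells were CD11c+CD64-, against 28.5%. At week 7, 91.1% of KLRG1+ and 89.6% of CD103+ cells were CD3+CD4+, against 87.6% of all cells. In the treated week 7 library 51.0% of KLRG1+ cells were CD3+CD4+ and 32.2% CD3-CD90.2+, against 65.8% and 17.3% of all cells. The CD4- part of the CD3-CD90.2+ phenotype, which leaves out cells resembling T cells with little CD3, went from 38.6% of cells at week 0 to 1.12% at week 4 and 0.831% at week 7. Its rank correlation with week was -0.929 over 8 libraries (exact p = 0.00223, adjusted over 2 parts p = 0.00446; Pearson r = -0.877, exact p = 0.000744). Without weeks 0 and 7 it was -0.829 (exact p = 0.0583), with a Pearson r of -0.845 (exact p = 0.0111). The part was picked after the whole phenotype had missed (rank correlation -0.643, exact adjusted p = 0.144). These are shares of all cells, measured beside a growing T cell share. Among CD3- cells the CD4- part was 6465 of 16634 at week 0, 201 of 8002 at week 4 and 99 of 1422 at week 7. Its trend among CD3- cells was not tested.

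The treated week 7 library held fewer CD11b+Ly-6G+ and more CD3-CD90.2+ cells than the untreated one. A larger T cell share without treatment would lower all other cells alike, but among CD3- cells the ratios were 0.0364 and 2.66, with intervals apart. The opposite directions are not separate results. CD11b+Ly-6G+ cells were 45.4% of untreated and 1.65% of treated CD3- cells, and a fall in that share raises the others. The ratio was 0.0935 for CD11b+Ly-6C+CD64+ cells and 1.35 to 1.62 for the remaining phenotypes. The 2.66 is thus in part set by the fall in CD11b+Ly-6G+ cells. Weaker Ly-6G staining would leave CD11b+ cells without other markers, and these were 1.05% (0.881 to 1.25) of treated cells against a gap of 4.93 percentage points. A difference between pools that is not the treatment cannot be told apart, because there was 1 treated pool, although the lowest untreated share of weeks 5 to 7 was 3.76%. An effect of IL-12p40 neutralisation on neutrophils is therefore a hypothesis that 1 pool leaves open.

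At week 6 fewer cells passed as CD3+ than as CD4+, 55.9% against 75.1%. A lower CD3 signal on all CD4+ cells of that library may account for it: the 90th percentile of the CD3 centred log ratio on CD4+CD90.2+ cells was 0.84, below the lowest of weeks 2, 3, 4, 5 and 7 (1.34). A separate CD3-negative subset would widen the distribution, and its SD was 0.488, within their range of 0.455 to 0.677. Weaker staining and lower CD3 on the cells themselves would both shift the whole distribution, and neither was tested against the other.

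At week 0, 31.6% (30.1 to 33.3) of CD64+Ly-6C- cells carried CD4, against 4.80% (1.78 to 10.2) of CD11b+Ly-6G+ cells, in a library with 1 CD3+CD4+ cell. Antibodies sticking without specificity would raise other proteins with CD4. Between CD4+ and CD4- cells of this phenotype the largest ratio of median counts among CD3, KLRG1 and Ly-6G was 1.33, against 10.3 for CD4. This comparison cannot decide the question, because the cells were split on CD4 itself. The centred log ratio used for the split also cancels a rise shared by all antibodies. A droplet shared with a CD4+CD90.2+ cell holds that cell's CD90.2 counts too, but 43.1% of the CD4+ cells of this phenotype, 450 of 1045, had fewer than the 5th percentile of CD4+CD90.2+ cells without myeloid markers. For the other 56.9% shared droplets stay open, as they do in the other 8 libraries, where median CD90.2 was 1.31 to 15.6 times as high in CD4+ as in CD4- cells of this phenotype. CD4 on some macrophages at week 0 may account for the part with few CD90.2 counts, as a hypothesis, and other sources of CD4 signal were not tested.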
